A study of Homo sapiens with 2 samples.

How the data were processed

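ATAC-seq libraries from Huh7 cells were analysed, 1 infected with a FLAG control lentivirus and 1 with a VPS72 lentivirus, grouped by the genotype and title given in the labels. The series' design text speaks of RNA-Seq, but the series type, the sample titles, the genomic DNA named as the molecule and the files are those of ATAC-seq, and the values were treated as such. The vector and the form of its VPS72 insert are not given. Per the labels' protocols, the virus was packaged in HEK293T cells, infection lasted 24 h, and 50000 nuclei were incubated with a Tn5 tagmentation enzyme and amplified by PCR with a cycle number set by real-time PCR. The submitters' processing notes name FastQC, Trimmomatic and BWA, and the builds hg19 and hg38. Versions, the role of each build, the size limits of the fragment classes, the handling of duplicates and any shift of Tn5 cut positions are not given in the sources used here.

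For each library the authors deposited counts of nucleosome-free reads and counts of mononucleosome reads per transcription start, per the file headers without scaling. These are whole numbers, and 93.2% (FLAG) and 93.3% (VPS72) of nonzero nucleosome-free counts were even, as when both mates of a pair are counted, but only 76.3% and 77.4% of mononucleosome counts. A further deposited table gives, per the file headers, the mean signal per base in 3 segments of a 400 bp window around each start. Multiplying this signal by 150 bp (upstream and downstream) and 100 bp (centre) returned whole numbers for 100% of 57564 rows at a tolerance of 1e-06, and these are called cuts here. The same table holds the authors' log2 mean coverage and a log2 nucleosome-free score. The score equals the log2 of the central signal, plus 1, minus the log2 of the summed flanking signals, with 1e-06 added to each signal, and this formula returned every deposited value to within 5.15e-14. The upstream and downstream order of the segments was checked on starts lying 100 to 150 bp apart, and held in 539 of 539 and 536 of 536 pairs.

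The files carry UCSC known gene transcripts, NCBI gene IDs and symbols, 48838 distinct starts with 22257 symbols. Only 3.76% of genes had a start within 1000 bp of their GRCh38 gene start, so positions are given as hg19, the other build in the notes. No hg19 annotation was used here, so exons and UTRs are not assigned. The RefSeq gene table of GRCh38.p14 served for gene types (39703 starts matched by gene ID) and for the order of neighbouring genes. The counting window is wider than 400 bp. Log2 ratios of neighbouring starts correlated at 0.995 when the starts were up to 100 bp apart, 0.265 at 1500 to 2000 bp and 0.029 at 2000 to 3000 bp. Reads near several starts are therefore counted at each, the file totals are not library depth, and genes with starts less than 2000 bp apart are named as sharing a window.

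Counts were scaled to the file total (CPM). Each gene was represented by its start with the most reads, and genes with at least 20 reads of the class over both libraries were tested. Log2 ratios (VPS72 over FLAG) used a pseudocount of 0.5. With 1 library per group no test between groups was possible, and no p-values are given across genes. Exact conditional binomial 95% intervals were computed on fragments, taken as reads divided by 2 and rounded up. Where only 1 mate was counted this gives too few fragments, and so too wide intervals and simulated spreads, mainly for mononucleosome reads. Intervals for cuts treat each cut as independent, and where an explanation rests on them a wider interval, with every 2 cuts taken as 1 fragment, is also given. PCR duplicates are not independent molecules, so the intervals cover counting error only. Intervals for sums over many starts are too narrow, because windows overlap. Counts of genes past 2-fold were set beside 100 simulations of fragment sampling, around 1 common ratio or around the ratio of genes in the same of 20 bins of read number. List medians are relative to the median of all tested genes, with counting intervals from 1000 resamplings and percentiles among 10000 random lists matched in 20 bins. Scores were compared as deposited.

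Before the data were examined, 14 gene lists, the alternatives and the rule for named genes were fixed. The rule takes VPS72, ATF3, MTOR, RPTOR, SREBF1, SREBF2, FASN, ACACA, ACLY and SCD. It adds the 10 highest and 10 lowest protein-coding genes by the bound of the nucleosome-free interval nearest to no change, among genes with at least 50 reads, and the 5 highest and 5 lowest likewise for mononucleosome reads. From each list it takes up to 2 highest and 2 lowest members whose interval excludes the median of all genes. The lists cover VPS72 complexes and H2A.Z, ATF3 with AP-1 and the integrated stress response, mTORC1, de novo lipogenesis, cholesterol synthesis, fatty acid oxidation, hepatocyte identity, cell cycle, interferon response, ribosomal and housekeeping genes, blood markers, endothelial, stromal, neural and muscle markers, HEK293 markers and histones. Some members, such as TSC1, FLCN and NR1I3, were not analysed here, and some genes taken by the rule are not reported here.

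The calculation was tested on simulated data. In nucleosome-free reads with 200 of 17223 genes altered, the intervals recovered 38.5% of genes altered 1.5-fold, 69.0% of those altered 2-fold and 90.5% of those altered 4-fold. In mononucleosome reads of 14623 genes the shares were 22.0%, 59.0% and 85.5%. Intervals covered the true ratio in 96.1% to 96.5% of nucleosome-free genes. Alternatives were TMM scaling with edgeR, scaling to the total of both classes, minima of 1 and 100 reads, summing over the windows of a gene, a pseudocount of 2, a 1.5-fold threshold, subsets of starts for the share and the score, and Pearson's correlation. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.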

Results

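Chromatin accessibility around transcription starts was measured by ATAC-seq in Huh7 cells, an established human hepatocellular carcinoma line. ATAC-seq uses the Tn5 transposase to cut and tag open DNA. Short fragments come from nucleosome-free DNA, and longer fragments span a nucleosome. Cells were infected for 24 h with a lentivirus carrying either a FLAG control or VPS72, and 50000 nuclei were taken per library. VPS72 (YL1) is a subunit of the SRCAP and TIP60-EP400 chromatin complexes, which exchange the histone variant H2A.Z. There was 1 library per group, so no value has a replicate error, and every interval given covers counting error in these 2 libraries only. Over 48838 transcription starts, the FLAG library held 2669938 nucleosome-free and 1378264 mononucleosome reads. The VPS72 library held 3020313 and 1282880. A read near several starts is counted at each, so these totals are not library depth. The median start had 16 nucleosome-free reads in the FLAG library and 14 in the VPS72 library. The title of the study places VPS72 upstream of ATF3, mTORC1, SREBP1 and lipid synthesis, and the comparison asks where accessibility at promoters differed when VPS72 was overexpressed.

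The VPS72 locus was examined first, since VPS72 is the gene that was overexpressed. Nucleosome-free reads at the VPS72 start (gene ID 6944, chromosome 1, position 151162689, minus strand, hg19) were 64 in the FLAG library and 274 in the VPS72 library, a log2 ratio of 1.91 (95% counting interval 1.36 to 2.52) after scaling to the file totals. The difference lay downstream of the start, on the transcribed side. Cuts there numbered 33 and 310, an 8.98-fold ratio, against 36 and 35 in the upstream segment and 29 and 20 in the central segment. Mononucleosome reads at VPS72 were 22 and 28, with an interval of the log2 ratio from -0.79 to 1.73. TMOD4 (gene ID 29765), which encodes a muscle tropomodulin and is the neighbour of VPS72 on the side of its 3′ end, differed more. Its start at position 151148547 had 18 nucleosome-free reads in the FLAG library and 656 in the VPS72 library, a log2 ratio of 4.97 (4.07 to 6.15), and 4 and 149 mononucleosome reads, a log2 ratio of 5.16 (3.43 to 8.40). Within the 400 bp centred on that TMOD4 start, however, the libraries held 8 and 9 cuts, so the additional reads lay elsewhere in the wider counting window. The TMOD4 start at position 151148457, whose window overlaps that one, had 18 and 639 nucleosome-free reads (4.93, 4.03 to 6.12), and the one at position 151144833 had 6 and 7. Leaving out VPS72 and TMOD4, the 14 starts of other genes within 100 kb, among them those of SEMA6C, PIP5K1A, PSMD4 and ZNF687, held 1464 and 1522 nucleosome-free reads together, a log2 ratio of -0.12 (-0.27 to 0.03, too narrow since some of these windows overlap).

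**Figure D1:**
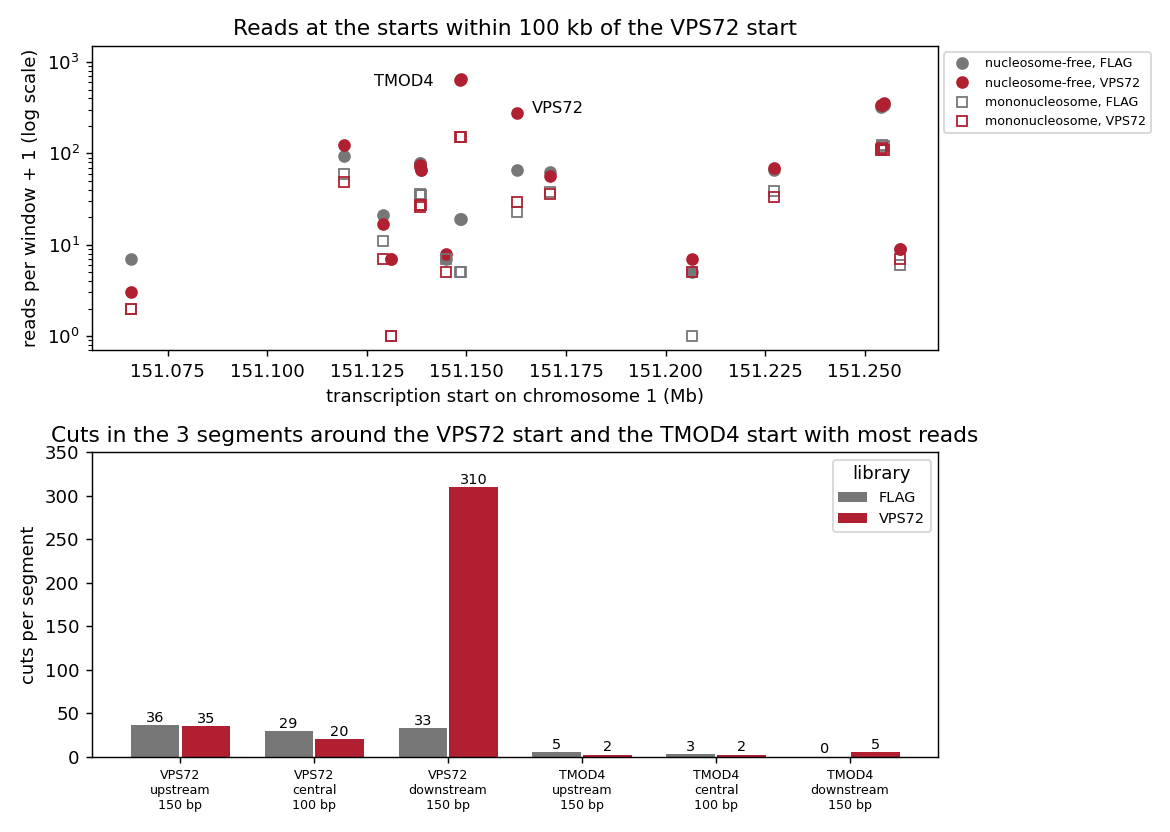
The upper panel plots reads per counting window plus 1, on a log scale, at each start within 100 kb of the VPS72 start, with filled circles for nucleosome-free and open squares for mononucleosome reads, and grey for the FLAG and red for the VPS72 library. The lower panel gives cuts in the upstream, central and downstream segments of VPS72 and TMOD4, where the VPS72 downstream segment holds 33 and 310 cuts.

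For the rest of the axis named in the study's title, no difference in nucleosome-free reads was detectable at this depth. ATF3, a stress-induced transcription factor, had 306 nucleosome-free reads in the FLAG and 328 in the VPS72 library, a log2 ratio of -0.08 (-0.40 to 0.25). MTOR, the kinase of mTORC1, had 174 and 240 (0.28, -0.12 to 0.70), and RPTOR, its scaffold partner, had 24 and 34 (0.32, -0.83 to 1.52). SREBF1, which encodes SREBP1, had 144 and 160 (-0.03, -0.50 to 0.45), and SREBF2, which encodes SREBP2, had 176 and 198 (-0.01, -0.44 to 0.42). Among the enzymes of fatty acid synthesis, FASN had 126 and 162 reads (0.18, -0.31 to 0.68), ACACA 224 and 250 (-0.02, -0.40 to 0.36), ACLY 106 and 156 (0.38, -0.14 to 0.91) and SCD 110 and 120 (-0.05, -0.60 to 0.50). FASN was the only gene of these 9 whose mononucleosome interval excluded 0, with 32 and 59 reads and a log2 ratio of 0.98 (0.09 to 1.98), but scaled to the total of both fragment classes its ratio was 0.78 and the interval included 0 (-0.10 to 1.79). The nucleosome-free intervals of all 9 include 0 and leave room for moderate differences, as the upper bounds of MTOR and ACLY show.

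Across the genome, nucleosome-free reads were compared for 17223 genes with at least 20 reads over both libraries. TMOD4 and VPS72 were the only genes beyond the largest deviation in 100 simulations of fragment sampling. TMOD4 deviated by 15.9 SD units, whereas the largest simulated deviation was 4.93. IP6K1, an inositol hexakisphosphate kinase, came next at 3.94 units, inside the simulated range. It had 58 reads in the FLAG and 154 in the VPS72 library, a log2 ratio of 1.22 (0.60 to 1.90), and 24 and 50 mononucleosome reads (1.15, 0.12 to 2.29). The other 7 genes named as highest by the fixed rule were NIBAN2 (1.18, 0.51 to 1.90), B3GALNT1, a glycosyltransferase gene (1.35, 0.43 to 2.40), SNAPC2, of the small nuclear RNA activating complex (1.09, 0.42 to 1.82), CDC73, of the PAF1 transcription complex (0.90, 0.42 to 1.40), MRPL15, of the mitochondrial ribosome (1.35, 0.39 to 2.45), LAMA2, a laminin chain (1.77, 0.36 to 3.59), and TOMM22, of the mitochondrial import receptor (1.20, 0.35 to 2.14).

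The 10 lowest nucleosome-free ratios by the same rule belonged to CROCC, the ciliary rootlet protein (-2.20, -4.01 to -0.80), MTCL1, a microtubule crosslinking factor (-1.89, -3.41 to -0.70), SMTNL1 (-1.79, -3.04 to -0.63), ATP5F1D, a subunit of ATP synthase (-1.50, -2.49 to -0.62), GAL, the precursor of galanin (-1.80, -3.30 to -0.55), ADAMTSL2 (-1.87, -3.52 to -0.55), MCIDAS, a regulator of multiciliated cells (-1.30, -2.13 to -0.54), ICOSLG, the ligand of the T cell costimulator ICOS (-1.56, -2.73 to -0.53), RNF187 (-1.20, -1.98 to -0.48) and LCN15 (-1.73, -3.24 to -0.47). CROCC had 42 reads in the FLAG and 10 in the VPS72 library, and ATP5F1D had 76 and 30. When the windows of a gene were summed, 3 intervals moved closer to no change without including it. They were those of CROCC (-1.51 to -0.13), MTCL1 (-2.26 to -0.26) and ADAMTSL2 (-2.36 to -0.29). The intervals of the other lowest genes stayed the same. Apart from TMOD4 and VPS72, the genes named as highest and lowest are the extremes of 17223 genes, and deviations of their size also arose in simulated sampling.

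In number, 190 genes were at least 2-fold higher and 828 at least 2-fold lower in the VPS72 library. Sampling of fragments around 1 common ratio gave 423 and 330 on average, and sampling around a ratio that depended on the read number of the gene gave 159 (at most 192) and 786 (at most 843). Relative to genes of like read number, a comparison chosen after the data had been seen, the split was 416 higher and 456 lower. The excess of lower genes thus lay in weakly covered windows, where the median log2 ratio was -0.47 in the lowest decile of genes (20 to 30 reads) and 0.06 in the highest (490 reads or more). The robust SD between genes lay inside the middle 95% of simulations in 9 of 10 deciles of read number and above it in 1, the decile of 49 to 82 reads, with 0.561 against 0.477 to 0.542. In the highest decile it was 0.162, against 0.146 to 0.162, and an additional SD of 0.1 between genes would have given 0.186 on average. Intervals excluded the ratio of like genes for 367 genes above and 381 below, both more than in any simulation (at most 352 and 373, and 310 and 317 on average). The simulations drew each gene independently, although windows of neighbouring genes can overlap, which makes such maxima too low. This small excess therefore does not establish differences at single genes.

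**Figure D2:**
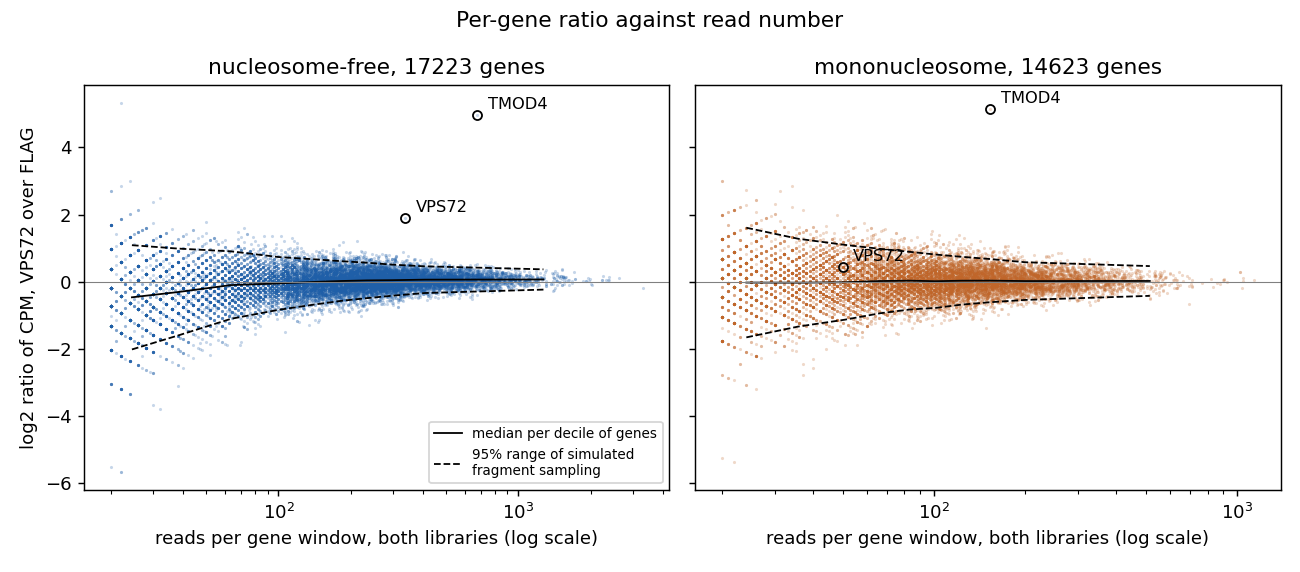
Each point is a gene with at least 20 reads in the fragment class, placed by its reads over both libraries (log scale) and its log2 ratio of CPM, VPS72 over FLAG. Solid lines join the medians of deciles of genes. Dashed lines mark a 95% range around them, a normal approximation from the robust SD of simulated fragment sampling. TMOD4 at 4.97 (nucleosome-free) and 5.16 (mononucleosome) and VPS72 at 1.91 and 0.44 are labelled.

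Gene lists fixed beforehand were compared by their median nucleosome-free log2 ratio relative to all genes, with its percentile among 10000 random lists matched on read number. The 23 genes of the VPS72 complexes and H2A.Z had a median of 0.09 (counting interval -0.06 to 0.19, percentile 71.2). Beyond VPS72 itself, KAT5, the acetyltransferase of TIP60, was the only member whose interval excluded the median of all genes, with 132 and 90 reads (log2 ratio -0.73, -1.31 to -0.16). The 30 genes of ATF3, AP-1 and the integrated stress response had a median of -0.05 (-0.17 to 0.07, percentile 2.98), 12 of them lay above the median of all genes, and no single member's interval excluded it. For the 44 measured genes of the mTORC1 pathway the median was 0.03 (-0.09 to 0.12, percentile 38.3). SESN3, a sestrin, was higher in the VPS72 library with 330 and 476 reads (0.35, 0.06 to 0.65), and 4 members were lower. By the bound of the interval, the lowest of these were NPRL2, of the amino acid sensing GATOR1 complex, with 134 and 82 reads (-0.88, -1.48 to -0.30) in a window shared with CYB561D2, and WDR24, of GATOR2, with 28 and 8 reads (-1.92, -4.05 to -0.31).

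Lipid genes showed small medians of both signs. The 30 tested genes of de novo lipogenesis and SREBP1 had a median of 0.08 (-0.04 to 0.20, percentile 70.5), with 18 above the median of all genes. ACSS2, which makes acetyl-CoA from acetate, had 254 and 404 reads (0.49, 0.16 to 0.82), and ACACB, the acetyl-CoA carboxylase of the mitochondrial surface, had 25 and 62 (1.12, 0.10 to 2.13). No member was lower by its interval. The 30 genes of cholesterol synthesis and SREBP2 had a median of 0.06 (-0.02 to 0.16, percentile 46.2). EBP, a sterol isomerase, had 222 and 323 reads (0.36, 0.01 to 0.73). The 26 genes of fatty acid oxidation and PPARA had a median of -0.05 (-0.18 to 0.14, percentile 13.4), with no member beyond its interval. Hepatocyte identity, with 34 tested genes, had a median of -0.01 (-0.10 to 0.17, percentile 40.6). Its apolipoprotein gene APOA1 had 76 and 50 reads (-0.78, -1.57 to -0.02).

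Of the remaining lists, cell cycle and DNA replication (38 genes) had a median of 0.06 (-0.03 to 0.17, percentile 65.1), with CCNE2 (0.50, 0.05 to 0.96) and MCM3 (0.37, 0.01 to 0.73) higher and AURKB (-0.88, -1.72 to -0.08) lower in the VPS72 library. Interferon and antiviral genes (27 tested) had a median of -0.05 (-0.21 to 0.17, percentile 36.6), and IFIT3 had 30 and 66 reads (0.95, 0.04 to 1.95). Ribosomal protein and housekeeping genes (40) had the lowest percentile of the lists, 0.72, with a median of -0.11 (-0.19 to 0.06), although RPS19 (0.67, 0.21 to 1.12) and RPL27 (0.82, 0.14 to 1.53) were higher and TUBB (-0.69, -1.25 to -0.11) lower. Replication-dependent histones (18) had a median of 0.13 (-0.09 to 0.22, percentile 86.8). Markers of other cells were weakly covered. Blood and immune markers (9 tested) had a median of -0.12 (-0.67 to 0.23, percentile 62.0). Endothelial, stromal, neural and muscle markers (17) had -0.17 (-0.52 to 0.27, percentile 46.8), the scaled value of a gene with equal reads in both libraries. Among them was DES, the muscle gene of desmin, at 26 and 8 reads (-1.82, -3.95 to -0.18). Markers of HEK293, the parent of the HEK293T line used to package the lentivirus (16 tested), had -0.29 (-0.64 to -0.01, percentile 5.98), the only nucleosome-free list whose counting interval excluded 0. Random lists of like coverage had a median of -0.09, inside that interval, and relative to genes of like read number the list's median was -0.13. By their intervals, 3 of its members were lower than the median of all genes. The lowest were WT1, sharing its window with WT1-AS, at 20 and 4 reads (-2.37, -5.73 to -0.27), and NEFH at 36 and 14 (-1.51, -3.04 to -0.21). Relative to genes of like read number the interval of WT1 included 0 (-5.24 to 0.22), and that of NEFH did not (-2.86 to -0.03). With 14 lists in each of 2 fragment classes, some low or high percentiles arise by chance. Shifts were simulated in lists of 30 genes, drawn only from genes with at least 100 nucleosome-free reads. A shift of 0.1 lay above the middle 95% of random lists in 3 of 10 trials. Smaller or more weakly covered lists were not simulated.

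**Figure D3:**
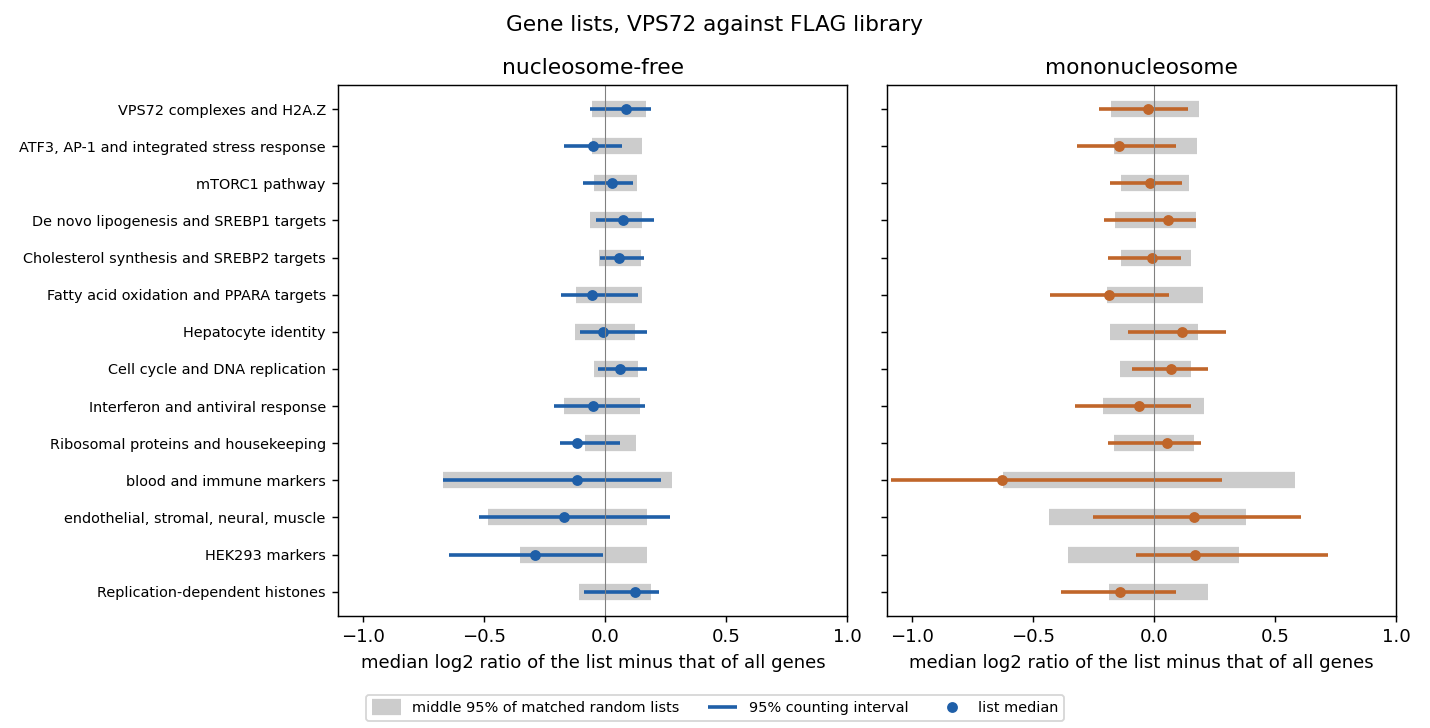
Points give the median log2 ratio (VPS72 over FLAG) of each list minus that of all genes, for nucleosome-free reads on the left and mononucleosome reads on the right, with 95% counting intervals as thin lines and the middle 95% of matched random lists as grey bars. Medians of the nucleosome-free panel run from -0.29 (HEK293 markers) to 0.13 (histones).

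Mononucleosome reads were compared for 14623 genes. TMOD4 was the only gene beyond all simulations, at 8.47 SD units against a largest simulated deviation of 4.88. The next highest by the fixed rule were TMED9, a cargo receptor of the secretory pathway, with 14 and 45 reads (log2 ratio 1.75, 0.55 to 3.28), PPP1R10, a nuclear targeting subunit of protein phosphatase 1, with 27 and 72 (interval 0.54 to 2.47) in a window shared with MRPS18B, NCK2, an adaptor protein gene, with 35 and 86 (1.39, 0.54 to 2.24), and ZNF532 with 38 and 88 (1.30, 0.51 to 2.17). The lowest were STC2, a secreted glycoprotein gene, with 110 and 39 reads (-1.38, -2.17 to -0.59), STUB1, a ubiquitin ligase, with 41 and 10 (-1.88, -3.73 to -0.52), ANKLE1 with 45 and 11 (-1.88, -3.42 to -0.50), TNRC6A, of the microRNA silencing machinery, with 53 and 16 (-1.59, -3.00 to -0.47), and BUD31, a splicing factor, with 57 and 18 (-1.53, -2.85 to -0.47) in a window shared with PDAP1. At 2-fold, 397 genes were higher and 482 lower, against 429 (at most 471) and 421 (at most 477) for sampling around 1 common ratio and 388 and 469 (at most 527) for sampling around a ratio by read number. Scaled by the total of both fragment classes, 241 were higher and 788 lower, because that scaling moved the median of all genes from 0.01 to -0.18. Intervals excluded the ratio of like genes for 261 genes above and 253 below, and simulations gave 247 and 255. The robust SD between genes lay inside the middle 95% of simulations in 8 of 10 deciles and above it in 2, among them the highest, with 0.245 against 0.215 to 0.237, near the 0.248 that an additional SD of 0.1 between genes would have given on average.

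For mononucleosome reads every list had a counting interval that included 0. ATF3, AP-1 and stress response genes had a median of -0.14 (-0.32 to 0.09, percentile 4.39), while FOSB, an AP-1 subunit (1.64, 0.03 to 3.42), and GADD45A, a stress-response gene (0.48, 0.03 to 0.94), were higher. Fatty acid oxidation and PPARA genes had -0.18 (-0.43 to 0.06, percentile 3.14), with PLIN2, a lipid droplet coat protein, at 119 and 57 reads (-0.95, -1.64 to -0.28) and ACAA1, a peroxisomal thiolase sharing its window with MYD88, at 208 and 119 (-0.70, -1.17 to -0.22). De novo lipogenesis genes had 0.06 (-0.21 to 0.17, percentile 72.8), with FASN higher, and SCD5 (-1.92, -4.46 to -0.15) and PGD (-0.72, -1.34 to -0.09) lower. The mTORC1 pathway had -0.02 (-0.18 to 0.12, percentile 40.4), with RPS6KB1, the gene of S6 kinase 1, which shares its window with TUBD1 (1.12, 0.12 to 2.29), and RRAGC, a Rag GTPase (0.74, 0.11 to 1.39), higher. Cell cycle genes had 0.07 (-0.09 to 0.22, percentile 81.7), with TOP2A (1.53, 0.34 to 2.94) and MYC (0.55, 0.01 to 1.09) higher and CCND1 (-0.83, -1.58 to -0.06) and CCNB2 (-1.64, -3.76 to -0.03) lower.

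The other mononucleosome medians were -0.03 for the VPS72 complexes (-0.23 to 0.14, percentile 37.8), -0.01 for cholesterol synthesis (-0.19 to 0.11, percentile 40.2), 0.12 for hepatocyte identity (-0.11 to 0.30, percentile 91.3) and -0.06 for interferon genes (-0.33 to 0.15, percentile 30.2). Ribosomal and housekeeping genes had 0.05 (-0.19 to 0.19, percentile 73.6). Histones had -0.14 (-0.38 to 0.09, percentile 6.33). Blood markers had -0.63 over 6 genes (-1.09 to 0.28, percentile 2.46), and endothelial, stromal, neural and muscle markers had 0.16 (-0.25 to 0.61, percentile 83.0). HEK293 markers had 0.17 (-0.07 to 0.72, percentile 81.4), or 0.00 without the minimum of 20 reads and 0.08 with a minimum of 100. LHX1 (1.54, 0.03 to 3.42) and EYA1 (1.26, 0.10 to 2.48), a pair of developmental regulators, were higher. LHX1 had only 10 and 28 mononucleosome reads. In nucleosome-free reads it was lower, with 50 and 24 (-1.22, -2.36 to -0.19).

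The balance of the fragment classes differed between the libraries. Nucleosome-free reads made up 66.0% of the reads of both classes in the FLAG library (exact binomial 95% interval 65.9 to 66.0%) and 70.2% in the VPS72 library (70.1 to 70.2%), a difference of 4.23 percentage points. When starts were ranked by their reads and divided into deciles, the most covered decile had a share of 67.0% in the FLAG library and 71.7% in the VPS72 library. In the lower 5 deciles the share was 0.580 to 1.35 points lower in the VPS72 library instead. Nucleosome-free reads in these weakly covered windows had log2 ratios between -0.52 (-0.60 to -0.44) and -0.45 (-0.47 to -0.42), and mononucleosome reads had ratios between -0.15 and -0.09. In the top decile the ratios were 0.06 (0.05 to 0.06) and 0.02 (0.01 to 0.03). These intervals are too narrow, because a read near several starts is counted at each, and the difference between the libraries has no replicate check.

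**Figure D4:**
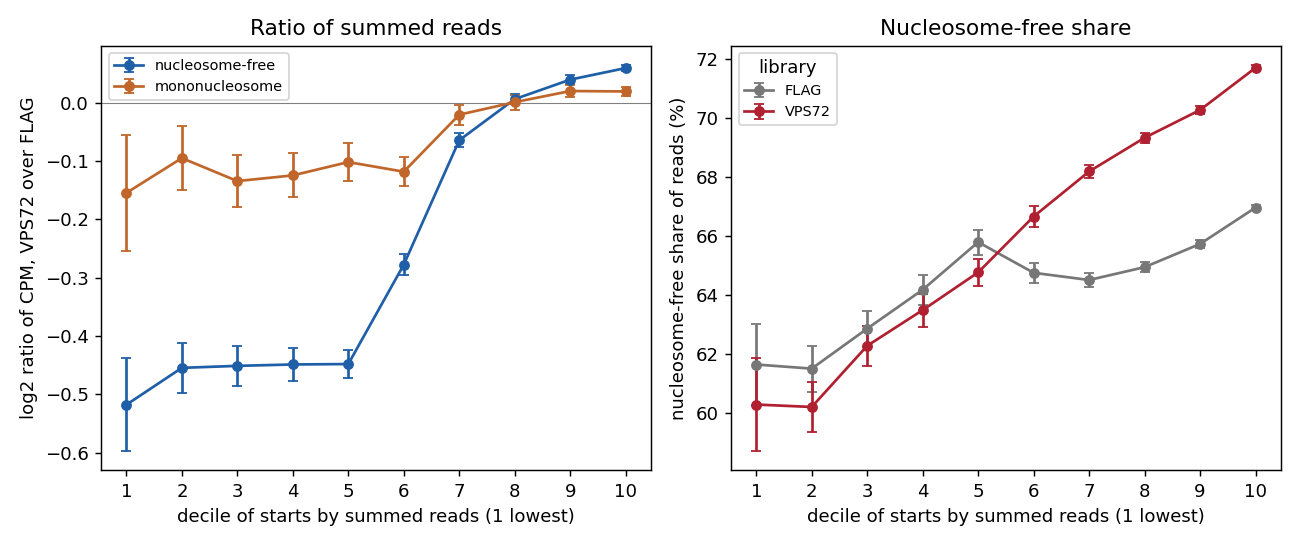
The left panel plots the log2 ratio of summed reads (CPM, VPS72 over FLAG) in each decile of starts ranked by reads, for both fragment classes, and the right panel the nucleosome-free share of reads (%, axis not from 0) in each library, all with 95% counting intervals. The nucleosome-free ratio runs from -0.52 in the lowest decile to 0.06 in the highest, and the share in the highest is 67.0% (FLAG) and 71.7% (VPS72).

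The deposited nucleosome-free score compares cuts in the central 100 bp of a start with those in the flanking segments. Its median over all starts was 0.40 in the FLAG and 0.50 in the VPS72 library, but at 29.0% and 32.6% of starts the central segment or both flanking segments held no cuts, and a small added constant sets the score there. The median difference per start was 0.00 over all starts, 0.01 over the 22275 starts with at least 20 reads in each class and 0.01 over the 13150 starts with at least 20 cuts in each segment. The upstream segment held 42.7% of the cuts in the FLAG and 42.9% in the VPS72 library, the central segment 31.5% and 31.7%, and the downstream segment 25.9% and 25.4%.

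The log2 ratios of nucleosome-free and mononucleosome reads were only weakly related across genes. Over 14451 genes with at least 20 reads in each class, Spearman's correlation was 0.052 and Pearson's 0.062, against a simulated Spearman value of 0.005 (-0.010 to 0.024) when both classes varied by sampling alone. After thinning to a common total the Spearman correlation was 0.045. Genes are not independent replicates, so no p-value is given. In most deciles the spread between genes was close to that of sampling, which keeps such a correlation low even where true differences agree. The low value therefore does not show that the classes moved separately. TMOD4 was far above other genes in both classes, and without TMOD4 and VPS72 the Spearman correlation was 0.052 and Pearson's 0.053.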

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

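Ratios against genes of like read number, restriction to starts at least 2000 bp apart and the correlation without VPS72 and TMOD4 were chosen after the data had been seen. All other alternatives were fixed beforehand. All 415 recomputed log2 ratios of the 83 named results and all 140 recomputed medians of the 28 list results stayed within their own counting intervals, which are wide for weakly covered genes. Scalings are not counted for lists, whose medians relative to all genes they leave as they are. For genes they are counted, although each moved all ratios of a fragment class by the same amount, too little to leave any of these intervals. Of the 140 medians, 13 had the other sign, in 9 of the 28 list results. With a minimum of 100 reads these were the mononucleosome medians of de novo lipogenesis (-0.09, from 0.06), interferon (0.03, from -0.06), ribosomal and housekeeping (-0.09, from 0.05) and endothelial, stromal, neural and muscle genes (-0.02, from 0.16). Whether an interval excluded 0, or for list members the median of all genes, was less stable. Counting a gene under each part of the rule, 68 did. Scaling bears on the 32 set against 0. All 32 still did under TMM scaling, and under scaling to both classes 1 no longer did, the mononucleosome ratio of FASN (0.78, -0.10 to 1.79), since that scaling lowers all mononucleosome ratios. When windows were summed 7 no longer did (ACACB, APOA1, IFIT3, TNRC6A, RPS6KB1, RRAGC and EYA1), and relative to genes of like read number 8 (SESN3, EBP, APOA1, CCNE2, MCM3, DES, WT1 and MYC); the causes were not tested. Spearman's correlation between classes stayed between 0.045 and 0.062. Pearson's was 0.062, and 0.105 with at least 100 reads in each class, or 0.061 without VPS72 and TMOD4. Numbers of genes past 2-fold depended on the settings. With a minimum of 1 read, 967 nucleosome-free genes were higher and 2450 lower, and 1843 and 2340 mononucleosome genes. With a minimum of 100 reads the numbers were 12 and 13, and 27 and 14, since fewer genes, with more reads each, were tested. At 1.5-fold they were 875 and 2046, and 1533 and 1502. Relative to genes of like read number, 416 nucleosome-free genes were higher and 456 lower, against 190 and 828 relative to all genes. Scaled to both classes together, 241 mononucleosome genes were higher and 788 lower, against 397 and 482, by the construction of that scaling. The nucleosome-free share in the top decile of starts was 67.0% and 71.7%, a difference of 4.73 points, and among starts at least 2000 bp apart the FLAG share was 66.0% and the difference 4.10 points. The median score difference was 0.00 as deposited. The log2 ratio of the fragment classes' counts in the wider window had a median difference of 0.16, which follows their totals. That ratio is a different measure, so the 2 values do not show how the score depends on processing. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth limits what could be seen: a 1.5-fold difference in nucleosome-free reads was recovered in 38.5% of simulated genes, and in 65.1% of those with at least 200 reads.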

Other observations

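The gene groups, the chromosome comparison and EEF1A1 were chosen after the data had been seen, as were the tests of each of the 3 patterns. Gene families defined by symbol showed small differences, given relative to the median of all genes. Proteasome subunit genes (36 tested) had the highest mononucleosome percentile among these groups, a median of 0.24 at percentile 99.6 of 2000 matched random lists, with 1783 reads in the FLAG and 1814 in the VPS72 library, but the pooled log2 ratio of these reads was 0.13 with an interval that included 0 (-0.01 to 0.26). Their nucleosome-free median was -0.05, at percentile 17.5. Mitochondrial ribosomal protein genes (81 and 79) had a nucleosome-free median of 0.08 (percentile 91.3) and a mononucleosome median of -0.02 (percentile 31.7), and zinc finger genes of the ZNF family (414 and 385) had, in the same order, medians of 0.05 (percentile 89.4) and -0.03 (percentile 8.25). HOX genes, which pattern the body axis, had in this order -0.17 (27 genes, percentile 13.2) and -0.12 (22 genes, percentile 22.1), and cytochrome P450 genes, many of them active in liver metabolism, likewise had -0.15 (41 genes, percentile 32.7) and -0.05 (27 genes, percentile 35.4). Olfactory receptor genes, which are silent in most tissues, had -0.17 (73 genes), at percentile 87.1 among genes as weakly covered as they were, for nucleosome-free reads, and -0.24 (45 genes, percentile 6.30) for mononucleosome reads. The nucleosome-free median of -0.17 of HOX and olfactory receptor genes is the scaled value of a gene with equal reads in both libraries. With 12 groups in 2 fragment classes, some extreme percentiles arise by chance.

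Weakly covered windows, those with fewer than 50 nucleosome-free reads, differed by chromosome in nucleosome-free reads. Relative to all such windows, chromosome 19 had a nucleosome-free log2 ratio of -0.24 (-0.29 to -0.19), chromosome 22 -0.16 (-0.24 to -0.08) and chromosome 20 -0.11 (-0.18 to -0.03), whereas chromosome 13 had 0.17 (0.06 to 0.27) and chromosome 18 0.14 (0.03 to 0.25). The mononucleosome intervals of the same windows included 0 on every chromosome, with -0.06 (-0.13 to 0.02) on chromosome 19 and 0.09 (-0.01 to 0.18) on chromosome 20. Over the 23 chromosomes the ratio went with the median distance between starts (Spearman 0.54, two-sided permutation p = 0.0084, Benjamini-Hochberg 0.0168 over 4 relations, and Pearson 0.57, permutation p = 0.00462, Benjamini-Hochberg 0.0168), and Pearson's value was 0.43 without chromosomes 13 and 4. The mononucleosome relation was 0.31 (Spearman, permutation p = 0.146) and 0.27 (Pearson, permutation p = 0.217). These values compare 2 libraries, not conditions. EEF1A1, the gene of translation elongation factor 1 alpha, had the most nucleosome-free reads of any start, 1663 in the FLAG and 1640 in the VPS72 library. The nucleosome-free log2 ratio of EEF1A1 was -0.20 (-0.34 to -0.06). Its mononucleosome reads were 436 and 256, a log2 ratio of -0.66 (-0.99 to -0.34). That deviation, 4.27 SD units, lay inside the simulated range, whose largest value was 4.88. Its nucleosome-free share of 82.7% lay at percentile 98.6 of 9902 starts with at least 200 nucleosome-free reads.

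Reads at the VPS72 and TMOD4 windows were far higher in the VPS72 library. Cuts at the upstream and central segments of the VPS72 start had a log2 ratio of -0.29 (-0.83 to 0.25, or -1.06 to 0.49 with every 2 cuts taken as 1 fragment), which argues against a more open endogenous promoter. Cuts are a different measure from the counted reads, not a part of them. In the VPS72 library the downstream segment of VPS72 held 310 cuts, and the wider window 274 nucleosome-free and 28 mononucleosome reads. A copy gain of the region would raise both measures. The upstream and central cuts would then rise as much as the reads of the window (1.91, 1.36 to 2.52), and cuts in the 400 bp at the TMOD4 start as much as its reads (4.97, 4.07 to 6.15). The TMOD4 cuts had 0.12 (-1.42 to 1.70, or -1.94 to 2.61), so both values argue against such a gain. The downstream segment alone had 3.17 (2.67 to 3.75, or 2.42 to 3.96), and the additional reads at TMOD4 lay outside the 400 bp around its start, in a window next to the 3′ end of VPS72. A candidate explanation is that these reads come from the VPS72 coding sequence carried by the lentivirus and aligned to the exons of the gene. Whether such DNA was integrated, unintegrated or left over from the carrier plasmid was not tested. The exons were not assigned, and the form of the VPS72 insert is not given in the labels.

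Weakly covered windows were lower in the VPS72 library. Between the lower 5 deciles of starts and the top decile, the log2 ratio differed by -0.51 for nucleosome-free and -0.13 for mononucleosome reads. The classes differed by -0.38 in this contrast (SE 0.013, too small since windows overlap). Unscaled mean reads per window of the lower 5 deciles were lower in both classes. They were 6.64 (FLAG) and 5.49 (VPS72) for nucleosome-free and 3.71 and 3.19 for mononucleosome reads. In the top decile the means were 254.6 and 300.2, and 125.6 and 118.5. In unscaled reads the difference between the classes thus lay mainly in the top decile. Scaled to the file totals, the top decile had ratios of 0.06 and 0.02, and the difference lay mainly in the lower 5 deciles. Where it arose therefore depends on the scaling. The contrast cannot decide whether a background level common to both classes lowered the weakly covered windows. An effect of VPS72 on chromatin, and a difference in tagmentation or library preparation that acts more on short fragments, cannot be told apart with 1 library per group.

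The nucleosome-free share was higher in the VPS72 library at strongly covered windows, by 4.73 points in the top decile. The log2 odds of a nucleosome-free read differed by 0.38 more in the top decile than in the lower 5 deciles. This argues against a size selection that changes these odds equally at all windows as the whole cause. Fragment lengths within the classes were not available. A selection by length that changes the odds unequally, because lengths differ between windows, was therefore not tested. The contrast is the same as that between the classes given above for weakly covered windows. An even background is no denser than the windows of the lower 5 deciles, whose mean reads were 2.72% (FLAG) and 2.07% (VPS72) of those in the top decile. Whatever its own share, it moves the share there by at most 2.72 points, which argues against dilution by an even background as the whole cause. A background that is denser at strongly covered windows, or combined with a size selection, was not tested, and an effect of VPS72 cannot be told apart from a difference between library preparations, since each group has 1 library.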
